A study of Mus musculus with 6 samples.

How the data were processed

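Poly(A) RNA of 6 BMDM libraries, 3 untreated and 3 pretreated with apoptotic cells, was sequenced in paired-end Illumina runs, per the labels' protocols. The submitters' processing notes name STAR 2.7.10a, Subread, featureCounts 2.0.3 and the mm10 build, with no role or order. The annotation release, strand setting, filters and treatment of reads that map to several genes are not given in the sources used here, so values of overlapping, antisense or near-identical genes are uncertain.

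The authors deposited 1 table with a signal value per gene and library, named as TPM, for 55291 genes, 24547 of them above 0 in some library. The deposited columns do not sum to 1000000: totals lay between 54732 and 92831. Multiplied by the merged exon length of GENCODE mouse release 21 and divided by 8.57, a factor shared by all libraries, the deposited signal gave whole read numbers in all 6 libraries for 23483 of 23870 genes with a read and a matched length (98.4%, tolerance 0.02 reads, against 4% by chance). Lengths matched 53292 of 55291 symbols. The deposited signal is thus a count per exon base that was not scaled for library size, and library totals followed depth by up to 1.7-fold. Depth was 19358254 to 32703615 reads per library. In the 6 columns, 0 were left unused and 0 rows named no gene.

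Each library was rescaled to sum to 1000000, which gives TPM, and the test fixed before the data were examined was then run unchanged, although it had been written for values already in TPM. Genes with at least 1 TPM in at least 3 libraries were tested with limma 3.58.1 (R 4.3.3; lmFit, and eBayes with trend) on log2(TPM + 1), AC pretreated minus untreated, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The median SE of a log2 difference was 0.21. Gene lists and cell type markers fixed before the data were examined were tested with camera (correlation of 0.01) where at least 5 members were tested, with Benjamini-Hochberg adjustment over 18 biology lists, and with camera with an estimated correlation and fry beside it. Shares of TPM were compared with exact permutation tests, whose smallest p for 3 against 3 is 0.1. All pairs of replicates differed beyond sampling noise by chi-square tests, so no library was counted as a duplicate. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

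The rule for named genes took, if no gene passed, the 12 smallest unadjusted p in each direction among genes whose groups did not overlap and whose higher mean was at least 5 TPM, without predicted or clone names. It added at most 4 members of each list with the smallest p and a fixed set of 17 genes. Some genes that the rule names are not reported here. Oas2, Gm23935, the cell type markers Cd4, Krt8, Krt18 and Hbb-bs, and the genes named in the first account of abundant transcripts fall outside it. So do genes named only in the additional observations. All were chosen after their values were seen.

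The test was tried on simulated data for this comparison, in 5 draws over 12331 genes on average with 200 changed genes each. It recovered 4.18% of genes changed 1.5-fold, 47.2% of those changed 2-fold and 97.6% of those changed 4-fold, and called 52 of 60505 unchanged genes. The simulation drew genes independently, with a common spread for both groups. It lacked the trends shared across genes and the wider AC spread of the real libraries, so its rates may not hold for them. Alternatives fixed before the data were examined were other pseudocounts, filters, scalings and variance models, the replicate number as a block, leaving out each library, and other list tests. Alternatives chosen after seeing the data were the values as deposited, voom on recovered reads with and without sample quality weights, a filter on recovered reads, protein-coding genes alone, removal of length and GC trends, and models of a batch of 4 libraries that held placental transcripts.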

Results

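Transcript levels were measured in mouse bone marrow-derived macrophages (BMDM), phagocytes grown from marrow precursors in culture. Of 6 poly(A) RNA libraries, 3 came from untreated cells and 3 from cells pretreated with apoptotic cells (AC). The origin, dose and timing of the apoptotic cells are not given in the sources used here. The deposited values gave back 22621104, 32703615 and 19358254 reads on genes for untreated replicates 1, 2 and 3, and 25326151, 21036494 and 21385113 for AC replicates 1, 2 and 3. Levels are given as TPM, the length-scaled share of all transcripts, recomputed so that each library sums to 1000000, as mean ± SD with n = 3 per group. Log2 differences are AC pretreated minus untreated on the log2(TPM + 1) scale, with their SE, and understate the change of low genes. Positions are on mm10. Nothing in the labels says that replicates came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

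Both groups had the transcript profile of macrophages. Apoe, which encodes a lipid carrier, was among the most abundant transcripts, at 24759 ± 1388 TPM in untreated and 24761 ± 3322 TPM in AC pretreated cells. Genes of lysosomal proteases were also abundant, with Ctss at 19397 ± 2900 and 18969 ± 1821 TPM and Ctsb at 11742 ± 645 and 12056 ± 780 TPM. C1qb, a subunit of the complement component that tags dying cells, stood at 11682 ± 1132 and 11466 ± 3122 TPM. Pearson correlations between libraries over 12603 genes lay between 0.948 and 0.987. The lowest were those between AC libraries (0.9479, 0.9650 and 0.9686). AC replicates 1 and 2 each correlated most with untreated replicate 2 (0.983 and 0.977). AC replicate 3 correlated most with untreated replicate 3 (0.976). The untreated libraries each correlated most with another untreated one. The AC libraries thus did not group together by this measure, and the cause was not tested. The first principal component held 41.9% of the variance and set AC replicate 1 (43.8) against AC replicate 3 (-38.5), with the untreated libraries between -7.05 and 9.14. The median SD per gene was 0.16 log2 units in untreated and 0.29 in AC pretreated libraries.

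The comparison between the groups asked which transcripts differ in macrophages pretreated with apoptotic cells. Of 35 tested interferon-response genes, 34 had a lower mean after AC pretreatment, with a mean log2 difference of -0.22 against a median of -0.07 over all genes. The list was called by camera with a preset correlation, and lost that call at adjusted p = 0.285 with an estimated correlation and at adjusted p = 0.358 by fry. Cxcl10, which encodes a T cell-attracting chemokine, averaged 20.4 ± 1.21 TPM in untreated and 13.1 ± 2.04 TPM in AC pretreated libraries (n = 3 each). Fos, an immediate-early transcription factor gene, averaged 101 ± 7.72 and 144 ± 10.8 TPM. Plin2, which encodes a lipid droplet coat protein, averaged 1218 ± 168 and 1601 ± 174 TPM. No single gene passed the test: of 12603 genes, 0 had an adjusted p under 0.05 by limma-trend, 0 in either direction and 0 with a 2-fold change. At an unadjusted p under 0.05 there were 164 genes, 53 higher and 111 lower, where chance alone would give 630. The values of the groups did not overlap for 557 genes (4.42%), where chance gives 10%. By voom on the recovered reads 0 genes passed, with 99 at an unadjusted p under 0.05, and by voom with sample quality weights 0 passed, with 1380. Of the 9502 genes whose higher group mean was at least 5 TPM, 8880 (93.5%) had a 95% interval of the difference inside 2-fold and 5515 (58.0%) inside 1.5-fold. These limits are on the log2(TPM + 1) scale, which understates the change of low genes, so shares in TPM could be lower.

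As no gene passed, genes were named by the smallest unadjusted p in each direction, 12 each way, and all had an adjusted p of 1.0 by limma. Over the 105 named genes of all parts of the rule, leaving out 1 library moved the log2 difference by over 1.5 times for 69 and turned its sign for 12. Among those with higher means after AC pretreatment, Fos (chromosome 12, 85473890 to 85477273) had a log2 difference of 0.50 ± 0.13. A further pair of immediate-early genes, Ier2 and Ier5l, had differences of 0.37 ± 0.16 and 0.52 ± 0.21. Angptl4 (chromosome 17, 33773750 to 33781830), which encodes an inhibitor of lipoprotein lipase, averaged 7.87 ± 1.48 and 12.7 ± 1.45 TPM, a difference of 0.64 ± 0.19. Plin2 (chromosome 4, 86648386 to 86670060) differed by 0.40 ± 0.16. The coagulation factor gene F7 and Procr, which encodes the protein C receptor, differed by 0.64 ± 0.23 and 0.45 ± 0.18. Gstp1, Gng11 and the noncoding Zfp652os differed by 0.35 to 0.46, and reads of Gstp1 can be shared with its close paralogs. Among those with lower means, Fcrl5, an Fc receptor-like gene, averaged 10.7 ± 0.989 and 6.06 ± 0.448 TPM, a difference of -0.72 ± 0.17. Cxcl10 (chromosome 5, 92346638 to 92348889) differed by -0.61 ± 0.17. Ifit3b (chromosome 19, 34607970 to 34613401), an interferon-induced gene whose reads can be shared with Ifit3, averaged 341 ± 12.3 and 257 ± 13.5 TPM, a difference of -0.41 ± 0.12. Ch25h, which encodes cholesterol 25-hydroxylase, differed by -0.97 ± 0.29, Spn by -0.83 ± 0.26, Cox20 by -0.87 ± 0.28, Cks2 by -0.58 ± 0.18 and Prr5l by -0.51 ± 0.15. On leaving out 1 library, Gng11 ranged from 0.24 to 0.56 and Cox20 from -1.02 to -0.57, while the other protein-coding genes of the 24 moved less than 1.5 times. The 24 were picked for small p and groups that did not overlap in these same libraries. That choice favours small movement, which is therefore no support for a difference. The other 6 of the 24 were small RNA genes (Snora41, Mir339, Mir7240, Mir7027, Snord32a and Snord98), several of which rested on fewer than 10 reads per library.

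**Figure D1:**
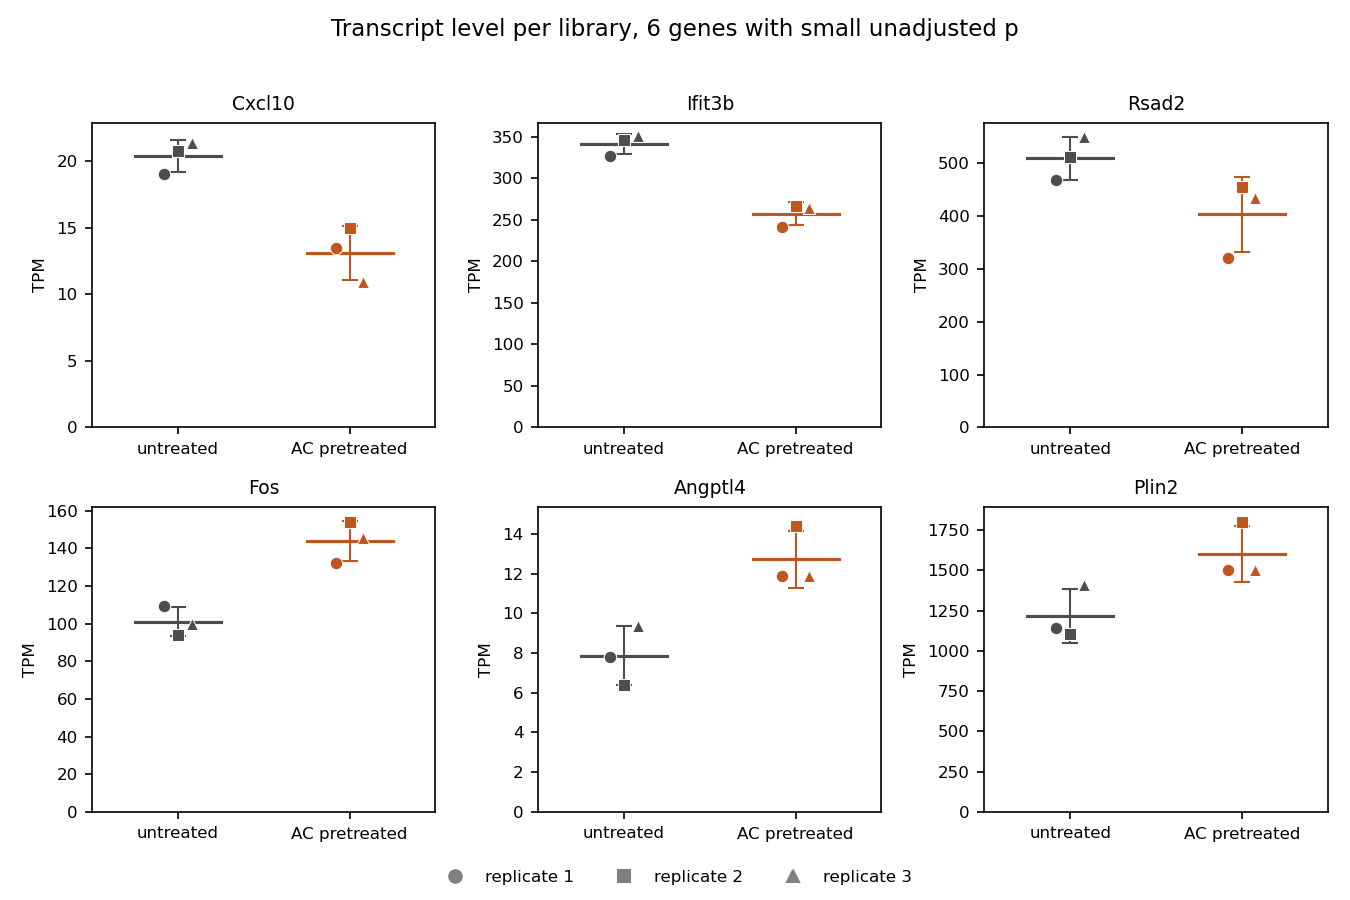
Level of 6 genes in TPM (linear vertical axes from 0) in each library, by group; symbols mark replicate numbers, horizontal lines the group means and error bars the SD (n = 3). The 3 AC pretreated libraries lie below the 3 untreated ones for Cxcl10 (13.1 against 20.4 TPM on average), Ifit3b and Rsad2, and above them for Fos, Angptl4 and Plin2. None of the 6 passed the adjusted test. All but Rsad2 were picked by a rule that required groups without overlap, so their separation follows from the choice.

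The interferon response list fell relative to the other genes by camera (adjusted p = 1.0e-08 over 18 lists, preset correlation of 0.01), with adjusted p = 0.285 with an estimated correlation. Of its 35 tested members, 34 had lower means, 0 passed over all genes and 0 adjusted over the list alone. Rsad2 and Cmpk2, which encode antiviral effectors, averaged 510 ± 40.5 and 281 ± 14.6 TPM in untreated and 403 ± 71.7 and 226 ± 37.4 TPM in AC pretreated libraries, differences of -0.35 ± 0.17 and -0.32 ± 0.15. Oasl1 differed by -0.34 ± 0.17 and Ifit1 by -0.20 ± 0.17. On leaving out 1 library these differences ranged from -0.44 to -0.19 for Rsad2, -0.44 to -0.20 for Cmpk2, -0.48 to -0.22 for Oasl1 and -0.35 to -0.08 for Ifit1. The member with a higher mean was Oas2 (0.03). The interferon response list was the 1 list of 18 whose library means did not overlap between the groups. Chance gives such separation in 10% of cases, so 1 of 18 lists is no more than chance would give. Fry of limma, which tests the members without the other genes, gave an adjusted p of 0.358 over 18 lists. The mean difference was -0.25 among the 4 libraries that held placental transcripts and -0.17 between the other 2 libraries.

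A set of 5 lists shifted upwards relative to the other genes by camera, and none held with an estimated correlation. Their mean differences were small, and the median over all genes was -0.07. The list of PPAR targets and fatty acid handling genes (adjusted p = 0.00102 by camera, adjusted p = 0.322 with an estimated correlation) had 13 of 19 tested members higher and a mean difference of 0.09. Fabp5, a fatty acid-binding protein gene, differed by 0.32 ± 0.17 and Acsl1, a fatty acyl-CoA synthetase gene, by -0.30 ± 0.18. The list of resolution and tissue repair mediators (adjusted p = 0.00126, adjusted p = 0.285 with an estimated correlation) had 10 of 18 higher and a mean of 0.08. Il1rn, which encodes the interleukin-1 receptor antagonist, and Vegfa differed by 0.42 ± 0.19 and 0.53 ± 0.26. The list of NRF2, heme and iron handling genes (adjusted p = 0.00406, adjusted p = 0.322 with an estimated correlation) had 12 of 20 higher and a mean of 0.05. Within it, Fth1, the ferritin heavy chain gene, averaged 9370 ± 1061 and 11217 ± 1531 TPM, and Hmox1 differed by 0.10 ± 0.12. The lysosome list (adjusted p = 0.00406, adjusted p = 0.322 with an estimated correlation) had 18 of 32 higher and a mean of 0.04. Members went both ways, 14 of them with lower means, and the protease gene Ctsl stood at 0.36 ± 0.19. The MHC class II presentation list (adjusted p = 0.00406, adjusted p = 0.464 with an estimated correlation) had 6 of 9 higher and a mean of 0.13. Cd74, the invariant chain gene, averaged 1849 ± 642 and 2354 ± 382 TPM, a log2 difference of 0.40, and H2-DMb2 differed by -0.55 ± 0.28. In these 5 lists 0 members passed over all genes and 0 adjusted over the list alone. On leaving out 1 library the differences ranged from 0.20 to 0.47 for Fabp5, -0.37 to -0.19 for Acsl1, 0.27 to 0.56 for Il1rn, 0.36 to 0.83 for Vegfa, 0.24 to 0.53 for Ctsl, 0.12 to 0.64 for Cd74 and -0.76 to -0.26 for H2-DMb2.

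Among the 4 libraries with placental transcripts, and between the other 2, mean differences were 0.10 and 0.06 for PPAR targets, 0.08 and 0.07 for resolution mediators, 0.08 and 0.00 for the NRF2 list and 0.04 and 0.02 for lysosome. For MHC class II presentation they were 0.28 and -0.17, so its direction turned. In the library means of these lists other than lysosome, untreated replicates 1 and 2 and AC replicate 1 all lay below the other libraries. Centred on the 6 libraries, MHC class II stood at -0.38, -0.11 and 0.29 in untreated and -0.04, 0.11 and 0.12 in AC replicates 1, 2 and 3. The higher set holds AC replicates 2 and 3, so this grouping and AC pretreatment are partly confounded for these lists. Calls ended without untreated replicate 1 (MHC class II, adjusted p = 0.811, and NRF2, adjusted p = 0.116), without AC replicate 1 (lysosome, adjusted p = 0.230, MHC class II, adjusted p = 0.225, and resolution mediators, adjusted p = 0.0607) and without AC replicate 2 (NRF2, adjusted p = 0.123).

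**Figure D2:**
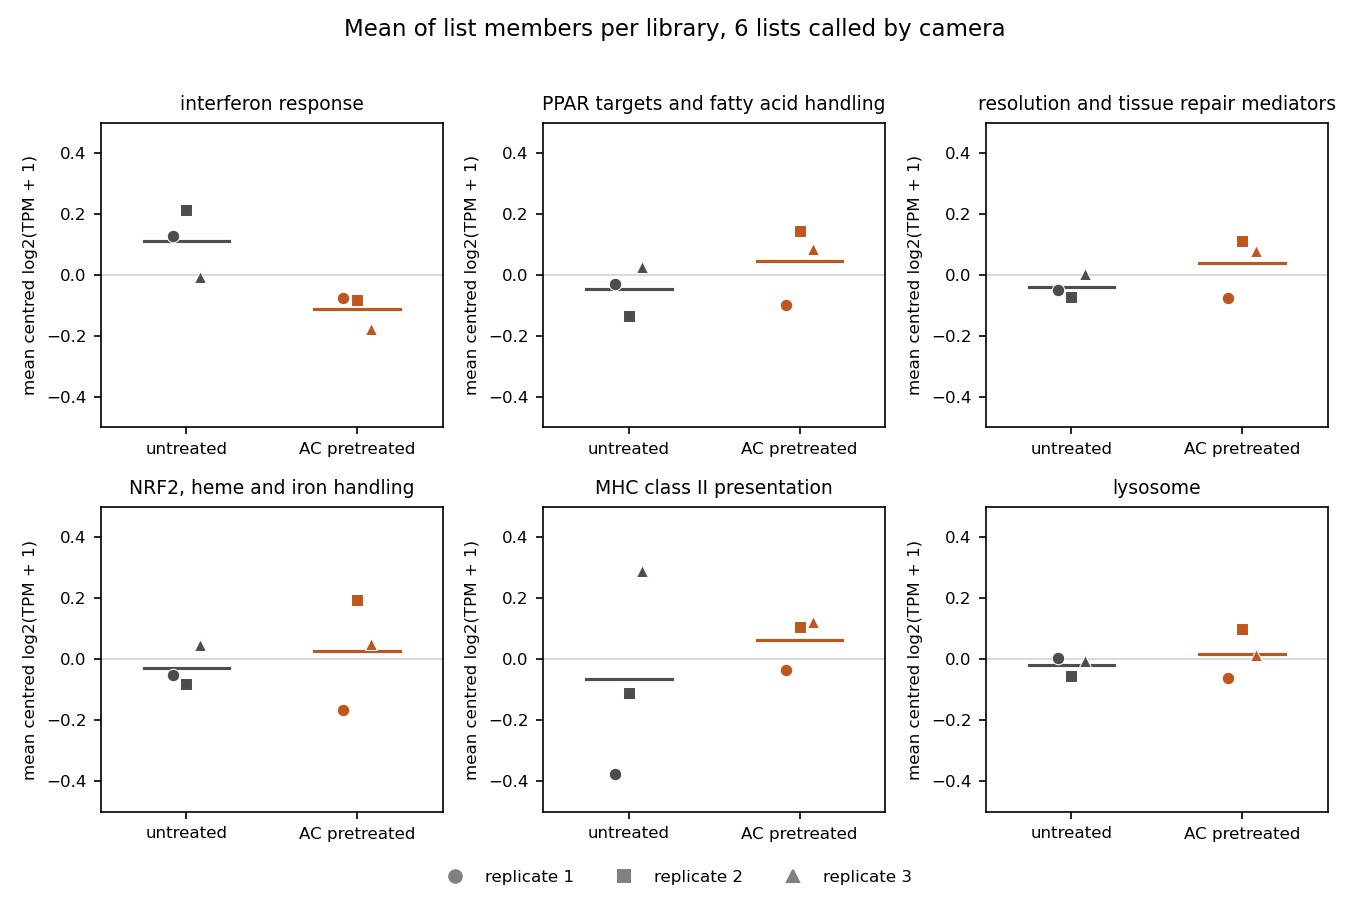
Mean over list members of log2(TPM + 1), centred per gene on the mean of the 6 libraries (vertical axes, log2 units), for the 6 lists called by camera with a preset correlation; symbols mark replicate numbers and horizontal lines the group means. The groups do not overlap for the interferon response list (untreated from -0.01 to 0.21, AC pretreated from -0.18 to -0.07) and overlap for the other 5. Chance alone separates the groups in 10% of cases.

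As no gene passed the test, none of apoptotic cell uptake or of the sterol response to engulfed cells did, and their lists did not pass either. The list of efferocytosis receptors and bridging molecules was not shifted (adjusted p = 0.128 by camera), with 10 of 25 tested members higher. Mertk, a receptor tyrosine kinase that binds apoptotic cells through bridging proteins, averaged 82.6 ± 6.05 and 84.2 ± 25.8 TPM (95% interval of the log2 difference -0.55 to 0.51), and Axl, a related kinase, 115 ± 11.7 and 104 ± 28.7 TPM. Thbs1, a bridging molecule gene, averaged 8.44 ± 1.44 and 18.4 ± 9.72 TPM, a difference of 0.89 ± 0.41. The AC libraries disagreed on Thbs1, with 7.32 TPM in replicate 1 and 22.8 and 25.2 TPM in replicates 2 and 3, and the difference ranged from 0.59 to 1.41 on leaving out 1 library. Among LXR target genes (adjusted p = 0.142), 9 of 18 were higher. Abca1, the cholesterol efflux transporter gene, differed by 0.13 ± 0.28 (95% interval -0.51 to 0.77) and Abcg1 by -0.00 ± 0.13 (95% interval -0.30 to 0.29). Nr1h3, which encodes LXR alpha, differed by 0.22 ± 0.13. Cholesterol biosynthesis and uptake genes had lower means for 21 of 23 tested members (adjusted p = 0.0638), with Insig1 at -0.24 ± 0.17 and Acat2 at -0.33 ± 0.21. Lower means were also the more common direction over all genes, whose median was -0.07. On leaving out 1 library the ranges were -0.33 to -0.09 for Insig1, -0.47 to -0.18 for Acat2 and 0.14 to 0.27 for Nr1h3, and signs turned for Mertk (-0.20 to 0.26), Axl (-0.37 to 0.04), Abca1 (-0.13 to 0.42) and Abcg1 (-0.07 to 0.04).

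The lists of inflammatory and cell cycle genes did not pass the test. Over all genes the median log2 difference was -0.07, so lower means were the more common direction there too. With median-of-ratios scaling that median was -0.008. Counts of members with lower means, in these and the following lists, are therefore not a shift by themselves. In the list of inflammatory cytokines and NF-kB targets 20 of 23 tested members had lower means (adjusted p = 0.0638), among them Tnf at -0.22 ± 0.17 and Ccl3 at -0.24 ± 0.15. Il1b differed by 0.41 ± 0.46, and the anti-inflammatory cytokine genes Il10 and Tgfb1 by -0.16 ± 0.22 and -0.06 ± 0.12. Of 30 cell cycle genes, 25 had lower means (adjusted p = 0.0638), with Ccnb2 at -0.63 ± 0.29 and Mki67 at -0.26 ± 0.36. On leaving out 1 library the ranges were -0.32 to -0.12 for Tnf, -0.33 to -0.15 for Ccl3, -0.08 to -0.03 for Tgfb1 and -0.97 to -0.41 for Ccnb2, and signs turned for Il1b (-0.02 to 0.80), Il10 (-0.39 to 0.05) and Mki67 (-0.55 to 0.13). The cell cycle mean was -0.27 among the 4 libraries with placental transcripts and 0.05 between the other 2, and the direction of its test turned without AC replicate 1 (adjusted p = 0.651). In the same sets of libraries the inflammatory mean was -0.19 and -0.02. Means also turned sign between these sets for efferocytosis (-0.09 and 0.26), LXR targets (-0.08 and 0.19), glycolysis (-0.06 and 0.11) and macrophage identity (0.07 and -0.04). Il6 and Arg1 were below 1 TPM in every library, with highest values of 0.241 and 0.437 TPM. MHC class I presentation genes had lower means for 11 of 12 members (adjusted p = 0.128), and genes of the unfolded protein and integrated stress response for 16 of 20 (adjusted p = 0.184), including Atf3 at -0.41 ± 0.15. Mitochondrial respiration genes had 20 of 24 lower (adjusted p = 0.558).

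Alternative activation genes (adjusted p = 0.0672) had 4 of 9 tested members higher, with Ear2 at 0.50 ± 0.25, and their mean (0.06) and median (-0.06) differed in sign. The same held for efferocytosis genes (mean 0.03, median -0.07). For arginine and polyamine genes (adjusted p = 0.184) and glycolysis genes (adjusted p = 0.128) the means of -0.02 and -0.01 were negative, while the medians of 0.04 and 0.04 and the direction of the test were positive. In the macrophage identity list (adjusted p = 0.713) 16 of 20 members had lower means, including Cx3cr1 at -0.72 ± 0.29 (-0.38 without untreated replicate 1) and Itgam at -0.26 ± 0.12, while Cebpb stood at 0.46 ± 0.19. The list mean was 0.04 and its median -0.10, because Lyz2, the lysozyme gene, differed by 2.46 ± 1.60. Lyz2 stood at 83.7 TPM in untreated replicate 1 and between 9270 and 12451 TPM in the other 5 libraries, so that difference rests on 1 library.

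As no gene passed the test between the groups, no marker of another cell type did, which does not exclude carried-over cells or RNA. Of 24 thymocyte and T cell markers, 21 were below 1 TPM in all 6 libraries, and the highest was Cd4 at 16.8 TPM. The neutrophil list (adjusted p = 0.543, 9 tested members) and the dendritic cell list (adjusted p = 0.543, 6 tested members) were not shifted by camera. Of the B cell markers 7 of 12, of the fibroblast and stromal markers 10 of 11, of the NK cell markers 6 of 8, of the mast cell and basophil markers 5 of 9 and of the epithelial markers 4 of 6 stayed below 1 TPM in all libraries. The epithelial keratin gene Krt8 averaged 0.370 ± 0.468 and 1.45 ± 0.626 TPM, a log2 difference of 0.86 ± 0.34 (adjusted p = 1.0 by limma). Krt18, below the filter, averaged 0.161 and 1.34 TPM, and each AC library was above each untreated one for both keratin genes. Globin Hbb-bs reached 7.44 TPM in AC replicate 2 and was 0 in replicate 3 of both groups. The 10 most abundant genes took 14.3 ± 0.527% of TPM in untreated and 17.0 ± 2.26% in AC pretreated libraries (exact permutation p = 0.1, 2-sided, the smallest this design allows). The AC shares were 16.0, 15.3 and 19.5% in replicates 1, 2 and 3. In AC replicate 3 the small RNA gene Gm23935 alone took 73936 TPM, against 9648 to 13452 TPM elsewhere. The lowest untreated share, 13.7%, was in replicate 1, where Lyz2 stood at 83.7 TPM. Shares without these genes were not computed. Mitochondrially encoded transcripts took 1.92 ± 0.225% and 1.93 ± 0.509% (exact permutation p = 1.0), and ribosomal protein genes 5.58 ± 0.102% and 5.18 ± 1.08% (exact permutation p = 0.6).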

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

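Alternatives on the deposited values, recovered reads (voom), length and GC, placental batch, gene type and 10 reads were chosen after seeing the data. None of the 6 called lists changed the direction of its test in these settings, though between the 2 libraries without placental transcripts, a pair with no test of its own, the mean of MHC class II was -0.17. Uncalled lists did where marked turned, and up to 8 of 105 named genes, none of which had passed, changed sign in a setting. The count of changed genes was 0 in 23 of 25 settings. It was 1 without the variance trend, higher and over 2-fold (Gm22279, a small RNA with 0 reads in untreated and 2 to 4 in AC libraries). It was 29 on values as deposited, 9 higher and 20 lower, 2 of them over 2-fold; the cause was not tested. Genes at an unadjusted p under 0.05 ranged from 77 to 1380. Depth limits genes of few reads. Over all genes the libraries of equal number did not deviate together (correlations -0.06, 0.01 and 0.17), although placental reads follow the numbers in both groups; with the replicate block 0 genes passed, 225 at an unadjusted p under 0.05, and 6 lists.

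The interferon response list was called in all 25 settings that keep the preset correlation, with 31 or more members lower and mean differences from -0.29 to -0.15. With an estimated correlation its adjusted p ranged from 0.146 to 0.882 over them, and no list was called in any. Camera with the preset correlation also gave the interferon list a small p in some splits that mix the groups, given below. The causes of the following changes were not tested. Values are adjusted p of the list named, and counts of lower lists include interferon. Of 18 lists, 6 were called (5 higher, 1 lower).
With an estimated correlation 0 were called, 0 higher and 0 lower: interferon 0.285, resolution 0.285, PPAR 0.322, lysosome 0.322, NRF2 0.322, MHC class II 0.464. With fry 0 were called: interferon 0.358, resolution, PPAR, lysosome, NRF2 and MHC class II 0.836, and efferocytosis, arginine and glycolysis 0.973 (turned).
With no filter 1 was called, 0 higher: PPAR 0.106, resolution 0.106, NRF2 0.132, MHC class II 0.202, lysosome 0.228. On values as deposited 1 was called, 0 higher: PPAR, MHC class II and resolution 0.0584, NRF2 0.0865, lysosome 0.0879, macrophage identity 0.182 (turned).
At 5 TPM 10 were called, 3 lower: inflammatory and cell cycle 0.0411 (lower), glycolysis 0.0411 and arginine 0.0492 (higher), and macrophage identity 0.965 (turned). With quantile normalization 3 were lower: cholesterol and cell cycle 0.0278 (lower), glycolysis 0.042 (higher), respiration 0.912 (turned). With median-of-ratios scaling 3 were lower: cholesterol 0.0286 and cell cycle 0.025 (lower), respiration 0.943 (turned).
With voom 11 were called, 8 higher and 3 lower: cholesterol and cell cycle 0.0217 (lower), LXR and alternative activation 0.0217 and efferocytosis 0.0498 (higher). With quality weights 3 were lower: MHC class I 0.000111 and inflammatory 0.0202 (lower), alternative activation 0.0219 (higher), MHC class II 0.0896 (call lost), cell cycle 0.678 and glycolysis 0.791 (turned).
Without length and GC trends 10 were called, 4 lower: cholesterol and cell cycle 0.0393 and inflammatory 0.0418 (lower), glycolysis 0.0361 (higher), respiration 0.816 and macrophage identity 0.942 (turned). With the replicate block added 3 were lower: cell cycle 0.0374 and cholesterol 0.0432 (lower), glycolysis 0.0249 (higher), respiration 0.83 and macrophage identity 0.986 (turned).
With a placental batch term 2 were lower (inflammatory 0.0464). In libraries with placental reads alone respiration was 0.191 and macrophage identity 0.8 (turned). In protein-coding genes 3 were lower: cholesterol and cell cycle 0.0426 (lower), efferocytosis 0.048 (higher). At 10 recovered reads 3 were lower: cholesterol 0.033 and cell cycle 0.0442 (lower), alternative activation 0.0147 (higher).
Leaving out 1 library gave 2 to 6 lists higher and 1 to 5 lower. The lowest and highest adjusted p were 5.77e-08 and 0.811 for MHC class II, 0.000507 and 0.123 for NRF2, 0.00406 and 0.23 for lysosome, 0.000209 and 0.0607 for resolution, 0.0123 and 0.434 for cholesterol, 0.0108 and 0.651 for cell cycle, 0.0376 and 0.309 for alternative activation, 0.00244 and 0.996 for inflammatory, 5.83e-05 and 0.964 for MHC class I, 0.0195 and 0.893 for glycolysis, 0.00371 and 0.834 for respiration, 0.0224 and 0.883 for stress response, 0.0236 and 0.551 for LXR and 0.0607 and 0.983 for macrophage identity. Directions turned without AC replicate 1 for cell cycle and glycolysis, without AC replicate 2 or 3 for MHC class I, respiration and macrophage identity, and without AC replicate 3 for stress response. Of 2610 values of single named genes and cell type lists, 76 moved beyond their spread or crossed a threshold.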

Other observations

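Tests in this part were chosen after the result was seen, with these exceptions. The main limma test and the fit without untreated replicate 1 were fixed before the data were examined. For the test that leaves out the 10 most abundant genes, the prediction was written before its result.

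Fos, Ier2 and Ier5l, immediate-early genes that respond within minutes to many stimuli, were among the 12 genes with higher means and the smallest unadjusted p within the rule for named genes. Over all genes, 8 of the 10 smallest p belonged to genes under 200 bases long. A list of 24 such genes, drawn up once these 3 were known, had 13 of 21 tested members higher and 8 lower, with a median log2 difference of 0.06 and 4 members at an unadjusted p under 0.05. Those 3 genes prompted the list, so the test was made on the other 18 tested members, of which 10 were higher, 8 lower and 1 at an unadjusted p under 0.05, with a median of 0.02. Camera on these 18 gave p = 0.175 with the preset correlation and p = 0.359 with an estimated correlation, so no joint shift beyond the 3 genes was detected. Ppbp, a platelet and myeloid chemokine gene singled out after its values were seen, averaged 1.01 ± 0.460 TPM in untreated and 3.21 ± 0.754 TPM in AC pretreated libraries (n = 3; adjusted p = 1.0 by limma).

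The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 0 changed genes and the highest other 15; any split reaches a count of 0, so 10 of 10 was fixed in advance and says nothing about chance. That other split, untreated 1, untreated 2 and AC 1 against the rest, also had 1865 genes at an unadjusted p under 0.05 against 164. It was singled out as the highest of 10, and differs from the real split by exchanging untreated 3 and AC 1. More genes thus separated along it than between the groups, and what it reflects was not tested. The real split gave 6 lists and the highest other 6, and 3 of 10 splits gave as many. The interferon response list had a mean shift of 0.22 in size in the real split and 0.18 in the highest other, and 1 of 10 splits gave as much. Camera with the preset correlation gave this list an unadjusted p of 5.6e-10 in the real split. In splits that mix the groups camera gave it 0.00011, 0.0008, 0.0016 and 0.0034, and 0.055 to 0.97 in the rest. A small p of this list by that test thus also arose under groupings other than treatment.

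Lyz2 (chromosome 10, 117277331 to 117282321), one of the most abundant macrophage transcripts, had 792 reads in untreated replicate 1 and 86328 to 133228 in the other 5 libraries; in TPM the median of those 5 was 123-fold above it. Lost reads passed to the neighbouring paralog Lyz1 are argued against, since Lyz1 stood at 63.2 TPM in that library and 32.5 to 60.5 TPM in the others, and so is a lower share of macrophages, since over 19 other macrophage genes the median ratio to the other libraries was 1.105. Lyz2 was the only protein-coding gene of 10498 at least 8-fold below all other libraries there (0 others), so a lost or disrupted Lyz2 allele in those cells may be a candidate explanation. It stays open, because the sources used here give no genotype and the reads were not analysed here. Cells of another origin under that label also stay open and were not tested; without that library 0 genes passed by limma and 106 had an unadjusted p under 0.05.

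Placental transcripts, from genes of the prolactin, pregnancy-specific glycoprotein, trophoblast and placental cathepsin families that macrophages are not known for, appeared in 4 libraries. Over 51 such genes there were 404 and 1335 reads in untreated replicates 1 and 2, 1023 and 3424 in AC replicates 1 and 2, and 5 and 4 in replicate 3 of each group; Prl3b1 reached 42.6 TPM in AC replicate 2. A response to apoptotic cells is argued against, since AC replicate 3 had 4 reads and untreated replicate 1 had 404. Over 28 genes, chosen by their reads in AC replicate 2, its profile correlated with that of the other 3 libraries at Pearson r of 0.908 or more. These are correlations across genes, which are not independent replicates. An outside source of placental RNA or reads may be shared by the 4 libraries. No separate placental profile was compared, so the correlation cannot tell 1 source from several. No biological explanation other than treatment was tested, and RNA carried over and reads carried over between libraries were not separated.

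The AC libraries differed more from each other than the untreated ones: over 6132 genes the median SD was 0.25 against 0.14 log2 units, a ratio of 1.83. Differences between libraries of a group followed exon length across genes, with Spearman rho of 0.534, 0.650 and 0.364 for AC and -0.408, -0.121 and 0.0932 for untreated pairs (1 and 2, 1 and 3, 2 and 3; the sign depends on the order), and GC content, with -0.530, -0.213 and 0.339 for AC and -0.185, -0.524 and -0.476 for untreated pairs. Removing length and GC trends left a ratio of 1.59, with SDs of 0.17 and 0.10, so those trends are argued against as the whole cause. Leaving out the 10 most abundant genes, among them the small RNA gene Gm23935 at 73936 TPM in AC replicate 3 and 9648 to 13452 TPM elsewhere, and scaling to a common median left 1.84, which argues against a few abundant genes. A variable response to the apoptotic cells stays open as an untested biological explanation, and RNA or library quality could also differ. Among genes picked out after their values were seen, Malat1 stood at 1036 TPM in AC replicate 3 and at 163 to 415 TPM elsewhere. Gm24187 stood at 426 TPM in AC replicate 3 and at 4.86 to 63.2 TPM elsewhere. Whether these levels reflect quality was not tested.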
